A study of Arabidopsis thaliana with 4 samples.

How the data were processed

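Small RNA libraries were made from 10-day-old seedlings of 2 genotypes, PORI and PORI rpt2a, with 2 libraries per genotype. They were assigned to groups by the sample titles, which write PORI rpt2a as PORIxrpt2a. Per the labels' protocols, total RNA was extracted with TRIzol and column-purified, small RNAs were recovered from a denaturing polyacrylamide gel, and libraries were made with an Illumina small RNA kit. Per the submitters' processing notes, the tools used upstream included CASAVA 1.8.2, FastQC 0.11.2, cutadapt 1.9.1, HTSeq and DESeq2, the genome build was TAIR10, and HTSeq and DESeq2 carried no version there. The aligner, the annotation release, the treatment of reads that map to several places or overlap several features, and strand use were not given in the sources used here. Reads shared by near-identical copies or by overlapping genes can therefore have been assigned to any of them, and values of such genes are uncertain.

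The authors deposited raw whole-number counts, 3 tables per library, each with 9 columns for read lengths from 18 to 26 nt per the file headers. There are 349 features for miRNAs, 38194 for genes and 31189 for TEs, of which 241, 29232 and 20414 had at least 1 count. The tables are not exclusive, since MIR genes of the gene table repeat miRNA reads, and of 6663 gene entries with at least 50 counts 50 held the same values as another entry in every library and length. The miRNA table held no reads of 18 nt. Gene names and classes came from a table of the TAIR10.1 assembly, matched by locus tag for 37898 of 38194 genes. It was used for names, classes and the order of genes only. TE identifiers were used as given, without families. Sequence-based checks such as GC content were not made.

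Counts per library over the 3 tables ranged from 3241463 to 5884528. A share of one library carries a 95% Wilson interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares were compared by an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333.

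Counts summed over lengths, and counts of 21, 22 and 24 nt reads, were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with group as the only term, TMM factors within a table, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-normalised within their table. A fold against a group at 0 was bounded with a floor of 3 counts over the group, and with 1 to 3 counts in a group the ratio of counts per normalised library size is given with an exact 95% interval. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists of a table, with at least 3 tested members. fry, which asks whether a list moves on balance one way and does not compare it with other genes, gave adjusted p-values of at least 0.0895 for every list. The interval of a difference of medians between miRNA lengths came from 10000 bootstrap resamples, chosen after the data were seen. Class shares were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.

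The lists were miRNAs (conserved families, triggers of secondary siRNAs, copper-responsive, phosphate and sulphate, age pathway, silencing feedback, auxin and leaf development, young families), genes (RPT2a with its neighbours and paralogue, TAS loci, phased-siRNA PPR and NB-LRR genes, auxin receptors, coding transcripts sensitive to RNA quality control, mRNAs of the silencing machinery, of RNA quality control, of the proteasome, of photosynthesis, of root and of seed storage, nuclear rRNA, chloroplast, mitochondrial, tRNA, snoRNA, snRNA and MIR genes) and TEs (ONSEN copies and single loci). Groups, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took RPT2a, its neighbours and paralogue, the 8 TAS loci, the largest changes past the threshold with non-overlapping groups (or, where fewer than 3 passed, the 5 smallest p-values), the 5 most abundant features of each table, and up to 4 members per list. It was extended to 22 nt TE reads and to the 21 nt miRNA call after the values were seen. The text names 71 of the 119 tested features the rule gave. This subset was chosen after values and their changes between settings were seen, and features near 0 whose sign changed were among those left out, so the named features look steadier than the rule's full set. Over the full set 38 of 119 features changed sign in at least 1 alternative, against 11 of the 71 named and 27 of the 48 not named.

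Alternatives were other size factors (DESeq2's, or the total of the 3 tables), other low-count filters, DESeq2 1.42.0, the replicate number as a block, a fold minimum, the gene table without structural RNA and organelle genes or without MIR genes, and each library left out in turn. Added after the data were seen were an adjusted p under 0.10, DESeq2 within length classes, tRNA genes summed by amino acid, and lists in 21 nt reads. The steps were tested on simulated counts with 22 changed miRNAs, or 200 changed features in each other table, some of which the filter removed, at the common dispersion of the real fits. For 2-, 4- and 8-fold changes, 0 of 7, 1 of 5 and 4 of 7 miRNAs were recovered (98 tested), 1.67%, 25.9% and 71.7% of genes (7443 tested), 1.67%, 25.9% and 69.6% of TEs (7418 tested), and 16.9%, 96.6% and 100% of TEs in 22 nt reads (1260 tested), with 0, 2, 1 and 7 false calls in the same order. All simulated features of a fit shared the same dispersion, and libraries differed only in depth and group. In the data PORI rpt2a replicate 2 stood apart, so these shares can overstate the recovery there. The list test called 20 of 20 lists of 20 genes shifted 2-fold and 0 of 20 unchanged lists. Genes were simulated as independent, so this does not show how the test fares on correlated lists. In the data the correlation was estimated at 0.366 for the TAS loci and 0.458 for the young miRNA families. It was 0.148 for the trigger miRNAs, and 0.0129 to 0.0242 for snoRNA, MIR, chloroplast and mitochondrial genes, slightly above the preset 0.01. For conserved, copper-responsive and age pathway miRNAs it was -0.00791, -0.199 and -0.0154. A correlation above the preset value is therefore not why the adjusted p-values of these last lists rose with an estimated correlation.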

Results

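Small RNAs of 10-day-old Arabidopsis thaliana seedlings were sequenced in 2 groups, a control line named PORI and PORI combined with rpt2a, with 2 libraries each. RPT2a is an ATPase subunit of the regulatory particle of the proteasome, and the series asks how it bears on post-transcriptional gene silencing and RNA quality control. The labels do not spell out what PORI stands for. The counts fall into 3 kinds of table, for microRNAs (miRNAs), annotated genes and transposable elements (TEs), each split by read length from 18 to 26 nt. The 3 tables together held 5806942 and 4809644 counts in PORI replicates 1 and 2, and 5884528 and 3241463 in PORI rpt2a replicates 1 and 2. Of these, 395530, 291475, 334074 and 125932 counts were in the miRNA table, in the same order, and 715242, 479710, 743563 and 228603 in the TE table. PORI rpt2a replicate 2 was the shallowest library, with 132 miRNAs detected against 196 to 213 in the other libraries. No label states that replicates came from separately grown plants, so p-values measure only the spread between these libraries, which may be technical.

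RPT2a (AT4G29040), the mutated gene, had 27 and 21 counts in PORI and 38 and 8 in PORI rpt2a, at a log2 fold change of 0.20 ± 0.44 (SE, n = 2 per group; edgeR adjusted p = 0.815). These are small RNA reads and not its mRNA, so they do not check the genotype labels. Its neighbours AT4G29030 and AT4G29050 had 10 and 2 counts in PORI and 7 and 3 in PORI rpt2a, and 1 and 5 counts in PORI and 1 and 2 in PORI rpt2a, respectively. Its paralogue RPT2b (AT2G20140) had 8 and 12 counts in PORI and 6 and 5 in PORI rpt2a. These 3 genes were too sparse to test. Without PORI rpt2a replicate 1 the RPT2a value was -0.30.

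The first comparison asked whether miRNA abundance differed with rpt2a. miR843 averaged 2481 ± 265 CPM in PORI and 37879 ± 20205 CPM in PORI rpt2a (SD, n = 2 each), a log2 fold change of 3.93 ± 0.78 (SE), and missed the threshold over all read lengths (adjusted p = 0.0756, edgeR). In 21 nt reads alone it rose, by 3.67 ± 0.74 on the log2 scale (adjusted p = 0.0438), the only call among 82 miRNAs tested. miR408-3p, which targets transcripts of copper proteins, averaged 13129 ± 3994 CPM in PORI and 56595 ± 51377 CPM in PORI rpt2a, and miR398b/c-3p, which targets copper/zinc superoxide dismutase transcripts, 17633 ± 1538 CPM in PORI and 54010 ± 39541 CPM in PORI rpt2a. Without PORI rpt2a replicate 2 their log2 fold changes moved from 2.11 to 0.63 and from 1.61 to 0.56. miR158a-3p, the most abundant miRNA over both groups though not within PORI rpt2a, averaged 187700 ± 16748 CPM in PORI and 116478 ± 139966 CPM in PORI rpt2a. miR403-3p, which targets AGO2, averaged 11939 ± 1306 CPM in PORI and 7187 ± 7872 CPM in PORI rpt2a. Without PORI rpt2a replicate 2 the log2 fold changes of miR158a-3p and miR403-3p turned to 0.20 and 0.095. miR159b-3p, a regulator of MYB transcripts, was at 0.10 ± 0.73, or -0.56 when scaled to the total of the 3 tables. Their adjusted p-values, and that of every other miRNA over all lengths, lay above the threshold.

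edgeR called 0 of 111 miRNAs, with 5 at an unadjusted p under 0.05 against 5.55 expected by chance, and DESeq2 called 2, miR843 and miR156f-3p, both higher. PORI rpt2a replicate 2 stood apart, with correlations of log2 CPM of 0.887, 0.901 and 0.902 with the other libraries, which correlated with each other at 0.967 to 0.984. It held 1.76% of its miRNA counts in miR158a-3p, against 17.9% to 22.3% in the other 3 libraries. Without PORI rpt2a replicate 1, 31 miRNAs were called (13 higher, 18 lower), the remaining mutant library being assumed to vary like the controls. The 21 nt call of miR843 ended without PORI replicate 1 (adjusted p = 0.998), without PORI replicate 2 (0.943) and under scaling to the total of the 3 tables (0.119), within a range of 3.22e-12 to 0.998 over all alternatives, while its log2 fold change without 1 library stayed between 3.52 and 4.18. With DESeq2 size factors miR843 passed over all lengths too (adjusted p = 0.0403), as it did without a low-count filter (0.00262), without PORI rpt2a replicate 1 (0.0365) and in DESeq2 (1.03e-06), within 1.03e-06 to 0.991. Scaling to the total of the 3 tables moved the median log2 fold change of all tested miRNAs from -0.19 to -0.85.

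**Figure D1:**
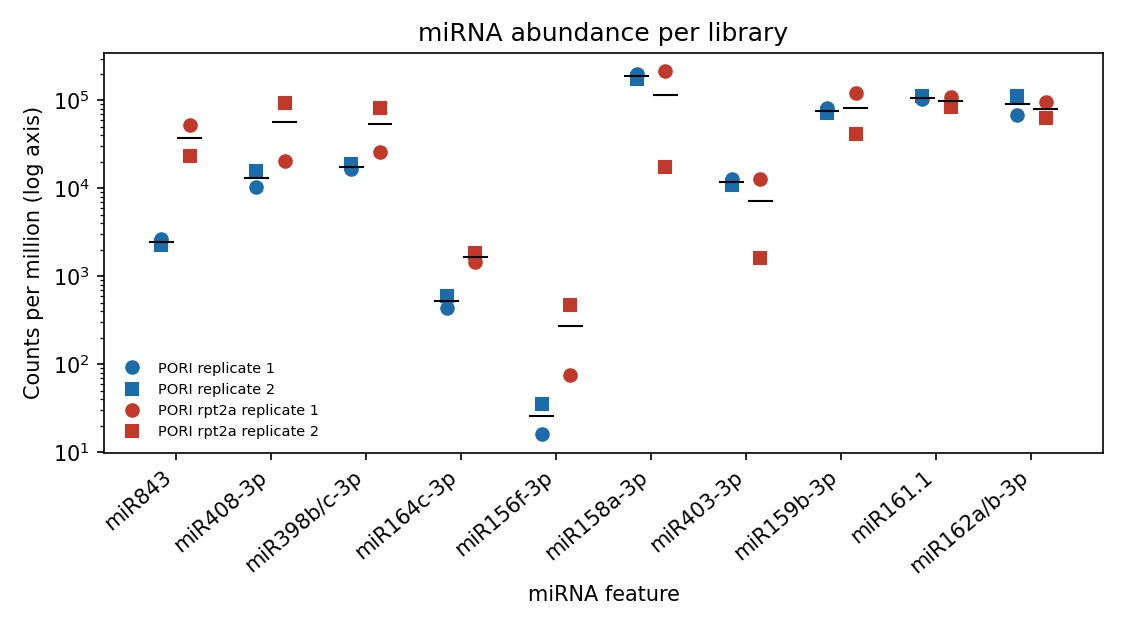
Abundance of 10 miRNAs in each library, in TMM-normalised CPM of the miRNA table on a log axis, with PORI in blue, PORI rpt2a in red and bars at the means of 2 libraries. miR843 lies higher in both mutant libraries, and miR158a-3p is low only in PORI rpt2a replicate 2, with 1.76% of its miRNA counts against 17.9% in PORI rpt2a replicate 1; under scaling to the total of the 3 tables miR159b-3p moves from above to below the control.

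Among miRNA lists, the copper-responsive miRNAs lay higher as a set, all 5 tested members having positive fold changes, with a median of 1.61 on the log2 scale (camera adjusted p = 0.0454; adjusted p = 0.353 with an estimated correlation). The rise was of 3p strands, since the members miR398b/c-5p and miR408-5p were near 0, at 0.11 ± 0.66 and 0.12 ± 0.79. These 5p strands lay above both controls in PORI rpt2a replicate 1 and below both in PORI rpt2a replicate 2. miR398a-3p, with a log2 fold change of 1.94 ± 0.86, and miR408-3p, with 2.11 ± 0.85, did not pass singly (miR398a-3p was at 0.53 without PORI rpt2a replicate 2), and 3 of 5 members stayed positive under scaling to the total of the 3 tables. The age pathway list held both strands of the families miR156, miR157 and miR172, which act in the juvenile to adult transition. It had 9 of 11 members above 0 (camera adjusted p = 0.0406; adjusted p = 0.353 with an estimated correlation). Its median was 0.79, or 0.039 under that scaling, and miR156f-3p was at 3.38 ± 1.11, or 1.61 without PORI rpt2a replicate 2. The 3p strands were all above 0. Except for miR156f-3p, however, they lay above both controls only in PORI rpt2a replicate 2. miR156a-3p, for example, was at 1230 and 1272 CPM in PORI and 1262 and 4584 CPM in PORI rpt2a. miR157c-3p was at 6001 and 14995 CPM in PORI and 5172 and 37472 CPM in PORI rpt2a. The other members were split, the miR156-5p entry at 0.43, miR156g at 0.72, the miR157-5p entry at -0.41 and miR172b/e-5p at -0.22. The conserved families lay higher relative to the other miRNAs but showed no general rise, with 35 of 63 members above 0 and a median of 0.13 (camera adjusted p = 0.0105; adjusted p = 0.353 with an estimated correlation). That median turned to -0.54 under scaling to the total of the 3 tables. miR166-3p, a regulator of HD-ZIP III transcripts, averaged 100813 ± 13583 CPM in PORI and 186209 ± 16948 CPM in PORI rpt2a.

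The list of miRNA families that trigger secondary siRNAs, with both strands counted, lay lower as a set. It had 13 of 15 members below 0 and a median of -0.52 (camera adjusted p = 0.0454; adjusted p = 0.577 with an estimated correlation). Its members included miR161.1 at -0.14 ± 0.65 and miR403-5p, also in the silencing feedback list, at -1.29 ± 1.07, or -0.46 and -4.61 without PORI rpt2a replicates 2 and 1. Young families also lay lower, with 19 of 25 below 0 and a median of -0.69 (camera adjusted p = 0.0454; adjusted p = 0.577 with an estimated correlation), although miR843, the largest of their positive values, belongs to them. The test compares a list with the other tested miRNAs. Young and conserved families held 25 and 63 of the 111 tested, so each was a large part of the other's background and their calls are not separate results. Outside the lists, miR8183 had 21 and 23 counts in PORI and 3 and 0 in PORI rpt2a, a ratio of 7.86-fold (exact interval 2.52 to 39.6) that covers counting error only. Of the lists not called, silencing feedback miRNAs, both strands of families that target DCL1, AGO1 and AGO2, had 6 of 7 members below 0 (camera adjusted p = 0.224). Among them miR162a/b-3p was at -0.19 ± 0.68 and miR403-3p at -0.73 ± 0.91, while miR168a/b-5p, the member above 0, was at 0.27 ± 0.65. Auxin and leaf development miRNAs had 12 of 23 above 0 (adjusted p = 0.0928), with miR164c-3p at 1.67 ± 0.69, and phosphate and sulphate miRNAs had 2 of 3 above 0 (adjusted p = 0.493). Adjusted over the list alone, 1 young-family miRNA passed, miR843, and 0 passed in each of the other 7 lists, as over all miRNAs. No call of the 5 lists held without PORI rpt2a replicate 2 (adjusted p = 0.103 to 0.776) or without PORI replicate 1 (0.0743 to 0.104). Without PORI replicate 2 the conserved and age pathway lists held, and without PORI rpt2a replicate 1 these and the young families. DESeq2 size factors ended the call of the trigger miRNAs (adjusted p = 0.0650), and scaling to the total of the 3 tables those of the young (0.158) and conserved families (0.0646).

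The second comparison concerned gene-derived small RNAs, first those of the TAS loci, whose transcripts are cut by miRNAs and turned into trans-acting siRNAs. All 8 TAS loci had negative log2 fold changes, with a median of -0.66, and lay lower as a set (camera adjusted p = 0.0209; adjusted p = 0.594 with an estimated correlation). TAS1A averaged 3540 ± 766 CPM in PORI and 1638 ± 1051 CPM in PORI rpt2a (SD, n = 2 each), a log2 fold change of -1.11 ± 0.60 (SE), and TAS2 2160 ± 217 CPM in PORI and 1189 ± 871 CPM in PORI rpt2a, or -0.86 ± 0.62. TAS1C, the most abundant, was at -0.66 ± 0.62, TAS1B at -0.37 ± 0.34, TAS3A at -0.67 ± 0.36, TAS3B at -0.38 ± 0.38, TAS3C at -0.95 ± 0.53 and TAS4 at -0.44 ± 0.46. No TAS locus passed singly, over all genes or adjusted over the list alone (0 and 0). All 8 stayed negative under each scaling. The set call ended without PORI replicate 1 (adjusted p = 0.128) and without PORI rpt2a replicate 2 (0.0751), when TAS4 turned to 0.050 and TAS1A, TAS2 and TAS1C moved to -0.56, -0.25 and -0.22, within a range of 0.000773 to 0.594 over the alternatives. Without PORI rpt2a replicate 1 these 3 loci were at -1.98, -1.91 and -1.28 and TAS3B at -0.020, and without PORI replicate 1 TAS3C was at -0.45.

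**Figure D2:**
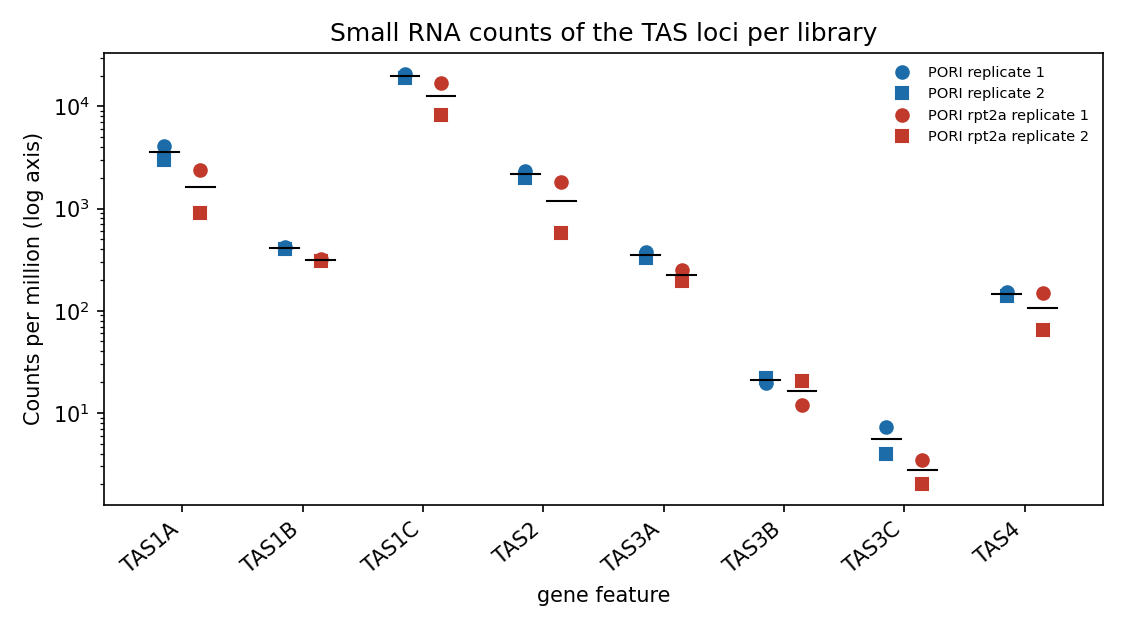
Small RNA counts of the 8 TAS loci in each library, in TMM-normalised CPM of the gene table on a log axis, with PORI in blue, PORI rpt2a in red and bars at the means of 2 libraries. The mutant mean lies below the control mean at every locus, by log2 fold changes from -0.37 at TAS1B to -1.11 at TAS1A, and PORI rpt2a replicate 2 is the lowest library at every locus but TAS3B.

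Other sources of secondary siRNAs were not called. Phased-siRNA genes encoding PPR proteins, which act in organelle RNA processing, had 9 of 17 members below 0 (adjusted p = 0.688), AT1G62590 being at -0.96 ± 0.35. Phased-siRNA genes of the NB-LRR immune receptor family had 5 of 5 below 0 (adjusted p = 0.126), with AT1G12290 at -0.77 ± 0.31. Auxin receptor genes had 2 of 3 below 0 (adjusted p = 0.908), and coding transcripts that yield siRNAs when RNA quality control fails 4 of 6 (adjusted p = 0.908). Small RNAs from mRNAs of the silencing machinery had 3 of 3 below 0 (adjusted p = 0.138), with DCL1 at -1.33 ± 0.50, AGO2 at -0.70 ± 0.44 and AGO1 at -0.50 ± 0.43. These moved to -0.80 without PORI replicate 2 (DCL1), and to -0.41 and -0.17 without PORI rpt2a replicate 2 and -1.18 and -1.04 without PORI rpt2a replicate 1 (AGO2 and AGO1). Proteasome subunit mRNAs had 10 of 14 above 0 (adjusted p = 0.688), with RPT6A at -1.27 ± 0.59 and its paralogue AT5G20000 at 2.33 ± 0.72, a pair that can share reads and moved to -0.85 without PORI replicate 2 (RPT6A) and 4.34 without PORI replicate 1 (AT5G20000). Photosynthesis mRNAs had 8 of 14 above 0 (adjusted p = 0.836), with RBCS2B at -0.85 ± 0.28. Of RNA quality control mRNAs 2 could be tested, with a median of 0.16, and of root mRNAs also 2, PYK10 at -0.62 ± 0.31 and PBP1 at -0.83 ± 0.34, and of seed storage mRNAs 0. Adjusted over the list alone, 0 members of each of these lists passed, as over all genes. The median and the test had opposite signs for photosynthesis mRNAs (median 0.050, tested Down), and the mean and the test for auxin receptor genes (mean 0.084) and quality-control-sensitive transcripts (mean 0.028).

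Over all gene-derived small RNAs, 2 of 8110 tested genes fell and 0 rose. Both are tRNA-Gly genes, AT5G59385, with 3158 and 2264 counts in PORI and 0 and 0 in PORI rpt2a, and AT5G45745, with 3174 and 2296 counts in PORI and 0 and 0 in PORI rpt2a. They were at least 1388-fold and 1400-fold lower, taking 3 counts over the group as the floor (adjusted p = 0.0296 for both, edgeR), and as tRNA copies can share reads their values are uncertain. The 41 tRNA-Gly genes summed to 12822 and 8468 CPM in PORI and 13914 and 2946 CPM in PORI rpt2a (without TMM factors), above both controls in one mutant library and below both in the other, a group difference of -0.337 on the log2 scale. The next genes did not pass. tRNA gene AT2G36280 was at least 125-fold higher (adjusted p = 0.0555), MIR166g at least 127-fold lower and tRNA-Gln gene AT5G50805 at least 60.7-fold lower (both 0.0686), all 3 from families of near-identical copies.

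At an unadjusted p under 0.05 there were 1868 genes against 405.5 expected, and the groups did not overlap in 57.1% of genes against 33.3% by chance. Genes counted in the same libraries are not independent, so any difference between the libraries, also one unrelated to genotype, can raise both values. DESeq2 called 447 (391 higher, 56 lower), edgeR without a low-count filter 669 (455 and 214), and edgeR without structural RNA and organelle genes 504 (438 and 66), while a minimum of 50 counts gave 0. With the replicate number as a block edgeR called 596 (492 and 104). The count was 12 without PORI replicate 1, 19 without PORI replicate 2, 2155 without PORI rpt2a replicate 1 and 1172 without PORI rpt2a replicate 2. The 2 tRNA-Gly genes passed in 10 of the 11 alternatives in which they were tested, with adjusted p-values from 4.07e-49 to 0.0894. Scaling to the total of the 3 tables moved the median log2 fold change of all genes from -0.036 to -0.25.

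Small RNAs from chloroplast genes lay lower as a set, with 100 of 133 members below 0 and a median of -0.47 (camera adjusted p = 1.57e-07; adjusted p = 0.342 with an estimated correlation). rpoC2 (ATCG00170), a plastid RNA polymerase subunit, was at -1.06 ± 0.31 and ndhC (ATCG00440), of the NDH complex, at -0.93 ± 0.29. snoRNA genes also lay lower, with 106 of 132 below 0 (adjusted p = 8.32e-06; adjusted p = 0.342 with an estimated correlation), AT5G01505 being at -2.15 ± 0.49. In the opposite direction, snoRNA gene AT4G08175 had 2 and 0 counts in PORI and 63 and 102 in PORI rpt2a, a ratio of 107-fold (exact interval 29.3 to 895) covering counting error only. MIR genes lay lower, with 119 of 178 below 0 (adjusted p = 0.00027; adjusted p = 0.367 with an estimated correlation), among them MIR158a at -1.26 ± 0.98, or -0.41 without PORI rpt2a replicate 2 and -3.52 without PORI rpt2a replicate 1, and MIR156f was at 2.12 ± 0.31 (edgeR adjusted p = 0.0686). Mitochondrial genes lay higher, with 63 of 96 above 0 (camera adjusted p = 0.00812; adjusted p = 0.506 with an estimated correlation), ATMG01330 being at 2.90 ± 0.51 and ATMG00360 having 60 and 31 counts in PORI and 3 and 0 in PORI rpt2a. The total of mitochondrial reads did not rise, at 0.568% and 0.544% of gene counts in PORI and 0.534% and 0.540% in PORI rpt2a. Without PORI rpt2a replicate 2 the mitochondrial list had an adjusted p of 0.0743.

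rRNA, tRNA and snRNA lists were not called. Of 5 nuclear rRNA genes 4 were above 0 (adjusted p = 0.723), with AT2G01020 at 0.78 ± 0.72, AT2G01010 at 0.32 ± 0.64 and AT3G41768 at 0.35 ± 0.70. The most abundant entry of the gene table, AT3G06365, an RNA gene next to an annotated rRNA gene in the gene order, held 19.1% and 22.4% of gene counts in PORI and 22.6% and 31.8% in PORI rpt2a (log2 fold change 0.79 ± 0.90), and AT2G03875, of the same kind, was at 0.97 ± 0.80. With PORI rpt2a replicate 2 left out both were at 0.066, AT2G01020 at 0.37, AT2G01010 at 0.0075 and AT3G41768 at -0.012. tRNA genes had 120 of 206 above 0, a median of 0.18 and a mean of -0.18 (adjusted p = 0.590, tested Down), and snRNA genes 18 of 26 above 0, a median of 0.39 (adjusted p = 0.908, tested Down). Adjusted over the list alone, 16 tRNA genes, 10 mitochondrial genes and 4 MIR genes passed, against 2, 0 and 0 over all genes, and 0 chloroplast, snoRNA, snRNA or rRNA genes passed either way.

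The third comparison asked whether TE small RNAs differed, first by read length. Reads of 22 nt made up 9.81% and 10.1% of TE counts in PORI (95% Wilson intervals 9.74 to 9.88 and 10.0 to 10.2) and 15.2% and 20.8% in PORI rpt2a (15.2 to 15.3 and 20.6 to 20.9). The group means differed by 8.04 percentage points, with SDs of 0.215 and 3.92 points (n = 2 each), and every mutant library lay above every control library (exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow). Reads of 24 nt, the main class of TE siRNAs, made up 59.8% and 58.1% in PORI and 55.3% and 45.5% in PORI rpt2a, and 21 nt reads 6.06% and 6.53% against 7.52% and 9.69% (exact permutation p = 0.333 for each). The group differences at 22, 24 and 21 nt were 5.27, -3.65 and 1.22 points without PORI rpt2a replicate 2, and 10.8, -13.5 and 3.39 points without PORI rpt2a replicate 1. The intervals cover counting error only. As a share of the 3 tables, 22 nt TE reads made up 1.11% ± 0.141 in PORI and 1.70% ± 0.325 in PORI rpt2a (exact permutation p = 0.333), the difference of 0.587 points falling to 0.357 without PORI rpt2a replicate 1. On that scale the groups overlapped at 24 nt, at 6.58% ± 1.11 in PORI and 5.10% ± 2.67 in PORI rpt2a (exact permutation p = 0.667).

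**Figure D3:**
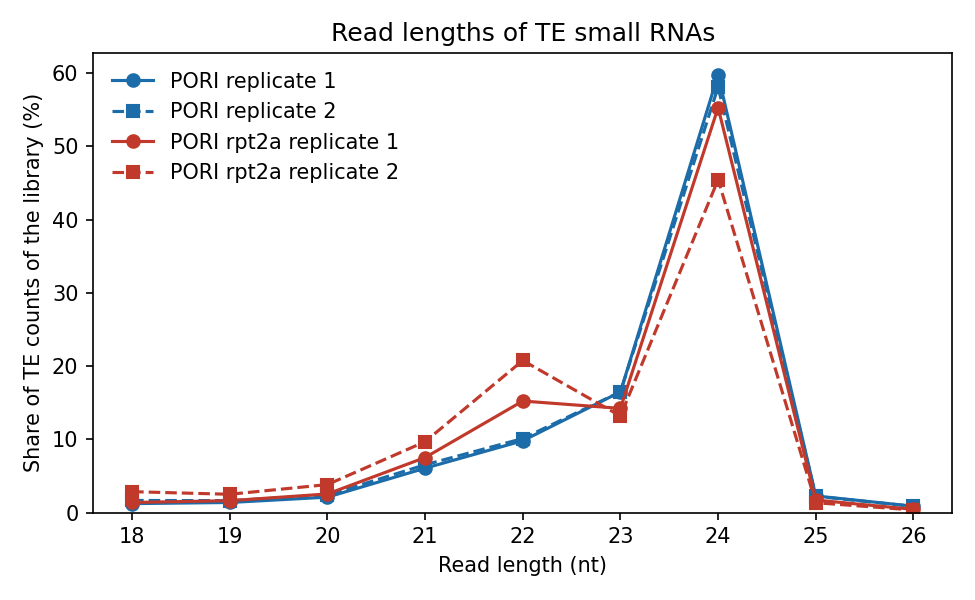
Read lengths of TE small RNAs, each point being the share of a library's TE counts, in percent, at one length in nt, with PORI in blue and PORI rpt2a in red. At 22 nt the mutant libraries hold 15.2% and 20.8% against 9.81% and 10.1% in the controls, and at 24 nt 55.3% and 45.5% against 59.8% and 58.1%.

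Single TEs were then compared in 22 nt reads, where 87 rose and 233 fell of 1462 tested (edgeR). AT3TE52310 rose by 3.16 ± 0.70 on the log2 scale (adjusted p = 0.00233), with 4 and 1 counts in PORI and 51 and 24 in PORI rpt2a, and AT2TE16815 by 2.90 ± 0.76 (adjusted p = 0.00765). AT3TE53870 and AT4TE24880 also rose, by ratios of 9.84-fold (exact interval 2.52 to 84.6) and 12.5-fold (exact interval 3.26 to 107). AT1TE66060 fell, with 35 and 21 counts in PORI and 1 and 0 in PORI rpt2a, a ratio of 93.9-fold (exact interval 16.2 to 3776), and AT5TE40480 with 42 and 23 counts in PORI and 2 and 0 in PORI rpt2a, a ratio of 54.5-fold (exact interval 14.5 to 459.7) (adjusted p = 5.96e-06 for both). AT3TE63405 and AT4TE50860 fell by ratios of 40.3-fold (exact interval 6.56 to 1656) and 17.3-fold (exact interval 5.41 to 88.6). The intervals cover counting error only.

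These 22 nt changes are relative to the other 22 nt TE reads. Scaling to the total of the 3 tables moved the median log2 fold change from 0.0030 to 0.93 and the calls to 478 higher and 14 lower, where all 320 TEs kept the sign of their fold change and 101 were still called in that direction. DESeq2 called 53 (44 higher, 9 lower). Of the 8 TEs named for these reads, AT5TE40480 was called in 7 of 8 alternatives and AT4TE24880 in 3 of the 7 that gave it an adjusted p, the fewest of the 8. Without PORI replicate 1 the count was 0, without PORI replicate 2 34, without PORI rpt2a replicate 1 644 and without PORI rpt2a replicate 2 396.

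Over all read lengths edgeR called 0 of 8211 TEs, with 1838 at an unadjusted p under 0.05 against 410.55 expected, and the groups did not overlap in 62.1% of TEs against 33.3% by chance. As for genes, differences between the libraries unrelated to genotype can raise both values. AT5TE40480 averaged 946 ± 34.7 CPM in PORI and 28.4 ± 22.9 CPM in PORI rpt2a (SD, n = 2 each), a log2 fold change of -4.81 ± 0.55 (SE), AT4TE40595 was at -4.78 ± 0.50 and AT1TE70850 at -3.42 ± 0.50. AT4TE18490 was at 3.19 ± 0.45 and AT1TE52990 at 2.19 ± 0.33, and all 5 shared the smallest adjusted p of 0.0891. Of the most abundant TEs, AT4TE14145 was at 1.19 ± 0.90, AT1TE54480 at 1.14 ± 0.71, AT5TE11315 at 0.18 ± 0.64, AT1TE54170 at 0.51 ± 0.63 and AT4TE34435 at -0.87 ± 0.69. With PORI rpt2a replicate 2 left out they were at -0.12, 0.53, -0.046, -0.12 and -0.35. The 8 copies of the heat-responsive retrotransposon ONSEN had 4 above and 4 below 0, a median of 0.019 and a mean of -0.048 (camera adjusted p = 0.740, tested Down), and EVADE (AT5TE20395), a mobile retrotransposon, was at -0.52 ± 0.60, 1 of 2 single loci tested (-0.20 and -1.34 without PORI rpt2a replicates 2 and 1). Adjusted over the list alone, 0 ONSEN copies and 0 single loci passed. DESeq2 called 519 TEs (493 higher, 26 lower) and edgeR without a low-count filter 993 (853 and 140). The count was 26 without PORI replicate 1, 17 without PORI replicate 2, 3179 without PORI rpt2a replicate 1 and 1217 without PORI rpt2a replicate 2, and scaling to the total of the 3 tables moved the median log2 fold change from -0.15 to -0.71.

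In the remaining length classes edgeR called 0 features. For miRNAs 45 were tested at 22 nt and 18 at 24 nt, with 1 at an unadjusted p under 0.05 in each and 0 calls by DESeq2 in each. For genes 1414, 2001 and 4575 were tested at 21, 22 and 24 nt, with 479, 680 and 1293 at an unadjusted p under 0.05 and 5, 45 and 102 calls by DESeq2. For TEs 842 and 6340 were tested at 21 and 24 nt, with 218 and 1357 at an unadjusted p under 0.05 and 0 and 195 calls by DESeq2. Scaling to the total of the 3 tables gave 526 genes at 22 nt (498 higher, 28 lower), 143 at 21 nt (129 and 14) and 243 TEs at 21 nt (237 and 6).

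The last comparison was of the composition of the libraries. miRNA counts made up 6.44% ± 0.531 of the 3 tables in PORI and 4.78% ± 1.27 in PORI rpt2a (SD, n = 2 each; exact permutation p = 0.333). Gene counts made up 82.4% ± 2.19 and 85.4% ± 5.22 (exact permutation p = 0.667), and TE counts 11.1% ± 1.66 and 9.84% ± 3.95 (exact permutation p = 1). Within gene counts, chloroplast reads made up 19.1% ± 0.377 and 15.8% ± 2.34 (exact permutation p = 0.333), and rRNA reads 21.6% ± 0.691 and 21.5% ± 0.0231 (exact permutation p = 1). TE genes made up 4.33% ± 0.657 and 6.01% ± 2.08 (exact permutation p = 0.667). The largest class, RNA genes annotated as misc_RNA, made up 26.3% ± 3.19 and 34.8% ± 8.70 (exact permutation p = 0.333). Its shares were 24.1% and 28.6% in PORI and 28.6% and 40.9% in PORI rpt2a, a difference of 8.44 points. AT3G06365 and AT2G03875 belong to it and not to the rRNA class. Shares add to a fixed total, so a rise of this class lowers the shares of others, chloroplast reads included. Without PORI rpt2a replicate 2 the gene and TE differences changed sign, to -0.732 and 1.49 percentage points, and the miRNA difference was -0.759 points, against -2.55 without PORI rpt2a replicate 1. The difference of TE genes, 1.68 points, was 3.15 and 0.214 without the same libraries, and that of chloroplast reads, -3.21 points, was -1.56 and -4.87.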

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

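The alternatives of an adjusted p under 0.10, DESeq2 within length classes, tRNA genes summed by amino acid and lists in 21 nt reads were chosen after seeing the data, and where a count moved with a setting the cause was not tested unless stated. With 2 libraries per group a library left out leaves a lone sample that is assumed to vary like the other group, and depth limits which features could be tested, the neighbours and the paralogue of RPT2a being too sparse. Same-numbered libraries deviated from their group means with positive correlations (miRNA 0.271, gene 0.158, TE 0.120, and 0.0635 to 0.662 within length classes), but with 2 pairs the libraries share only a number. Under the replicate block calls were 0 miRNAs, 596 genes (492 higher, 104 lower), 0 TEs, 9 genes at 21 nt, 3 at 22 nt, 91 at 24 nt, 1 miRNA at 21 nt, 234 TEs at 22 nt (69 higher, 165 lower), 1 TE at 24 nt, and 0 in the remaining length classes. The block gave 8 list calls, ending those of trigger miRNAs (adjusted p = 0.0670) and young families (0.0927), turned the tRNA (adjusted p = 0.866) and snRNA lists (0.790) and miR159b-3p (-0.10), and changed no other direction of a list or of a feature named here.

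Scaling to the total of the 3 tables gave 0 miRNAs at 21 nt, 143 genes at 21 nt, 526 at 22 nt, 243 TEs at 21 nt, 492 at 22 nt and 2 at 24 nt. It turned the snRNA list (adjusted p = 0.864), miR159b-3p (-0.56), AT1TE54170 (-0.26) and AT5TE11315 (-0.50), features whose fold changes were smaller than the shift of their table's median. DESeq2 size factors gave 1 miRNA and turned miR161.1 (0.031), and left the gene and TE counts at 2 and 0. No low-count filter gave 1 miRNA, 669 genes and 993 TEs, and a minimum of 50 counts 0 genes. DESeq2 gave 2 miRNAs, 447 genes and 519 TEs, and by length 2 miRNAs at 21 nt, 5 genes at 21 nt, 45 at 22 nt, 102 at 24 nt, 53 TEs at 22 nt and 195 at 24 nt, and turned miR161.1 (0.016). An adjusted p under 0.10 gave 1 miRNA, 751 genes (625 higher, 126 lower), 585 TEs (517 and 68), 208 genes at 21 nt, 451 at 22 nt, 512 at 24 nt, 51 TEs at 21 nt and 404 at 24 nt, the threshold itself being looser. Without structural RNA and organelle genes 504 genes were called, with tRNA genes summed by amino acid 424 (379 and 45), and without MIR genes 3, the third being AT2G36280. An estimated correlation gave 0 list calls. In 21 nt reads 7 lists were called, all of genes, and the nuclear rRNA (adjusted p = 0.620) and mitochondrial lists (0.880) turned. Without rRNA, tRNA and organelle genes in the total, the group difference of the miRNA share was -2.76 percentage points and that of 22 nt TE reads 0.860. That total kept the misc_RNA class.

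Over the 4 fits that left out a library, calls ranged from 0 to 31 for miRNAs, 12 to 2155 for genes and 17 to 3179 for TEs. By length they ranged from 0 to 43, 0 to 19 and 0 to 4 for miRNAs at 21, 22 and 24 nt, 0 to 469, 0 to 609 and 2 to 1551 for genes, and 0 to 233, 0 to 644 and 4 to 1692 for TEs. List calls ranged from 3 to 10. Group differences of shares ranged from -0.732 to 6.64 points for genes, -4.09 to 1.49 for TEs and -0.516 to 0.460 for rRNA. Adjusted p-values of lists that turned ranged from 0.285 to 0.773 (phosphate and sulphate), 0.0147 to 0.593 (auxin and leaf), 0.0489 to 0.796 (PPR), 0.652 to 0.995 (auxin receptors and quality-control-sensitive transcripts), 0.0743 to 0.995 (photosynthesis), 0.139 to 0.796 (nuclear rRNA), 0.0190 to 0.510 (tRNA), 0.0975 to 0.995 (snRNA) and 0.373 to 0.924 (ONSEN). Log2 fold changes of features that turned ranged from -1.19 to 0.050 (TAS4), -0.012 to 0.65 (AT3G41768), -0.30 to 0.50 (RPT2a), -3.42 to 0.20 (miR158a-3p), -0.88 to 0.67 (miR159b-3p), -0.34 to 0.069 (miR161.1), -0.52 to 0.34 (miR162a/b-3p), -2.88 to 0.095 (miR403-3p), -0.12 to 0.94 (AT1TE54170), -0.12 to 1.83 (AT4TE14145) and -0.046 to 0.32 (AT5TE11315).

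Of the 71 named features 60 kept their direction in every alternative. Leaving out 1 library moved the log2 fold change of 39 of them by over 1.5 times, 30 without PORI rpt2a replicate 2, 29 without PORI rpt2a replicate 1, and 10 and 8 without PORI replicates 1 and 2. This subset was picked after seeing such changes and leaves out features near 0 that turned. Over all 119 features of the rule, 1325 comparisons with an alternative gave 62 changes of sign, 123 values newly past the threshold and 21 no longer past it, and 38 features changed sign at least once. All 320 TEs called in 22 nt reads kept their direction in each alternative, and 320 (DESeq2 size factors), 101 (total scaling), 50 (DESeq2, which gave 178 of them an adjusted p), 224 (block) and 0, 34, 309 and 276 (without PORI replicates 1 and 2 and PORI rpt2a replicates 1 and 2) were still called.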

Other observations

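In 21 nt reads, the size of most miRNAs and secondary siRNAs, 7 of the gene lists lay lower in PORI rpt2a relative to other 21 nt gene reads, and none higher. They were chloroplast genes (camera adjusted p = 1.66e-14), MIR genes (2.83e-10), snoRNA genes (0.00038), TAS loci (0.00728), photosynthesis mRNAs (0.0257), NB-LRR genes (0.0268) and mRNAs of the silencing machinery (0.0387). An estimated correlation, other scalings and fits that leave out a library were not run here. All 13 gene lists tested had this direction, without passing for PPR genes (0.0542), quality-control-sensitive transcripts (0.0832), snRNA (0.114), tRNA (0.238), nuclear rRNA (0.620) and mitochondrial genes (0.880). The test compares a list with the other genes, so this is no fall of 21 nt gene reads as such. TE genes form no list, and their 21 nt share was 5.49% and 5.87% in PORI and 7.76% and 10.1% in PORI rpt2a. Scaling to the total of the 3 tables moved the median log2 fold change of 21 nt gene reads from -0.099 to 0.36. Of the 8 miRNA lists 0 were called in 21 nt reads (adjusted p = 0.201 to 0.690), so the 5 calls over all lengths ended.

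The tests of tRNA-Gly copies, size selection, a mislabelled control, miR158a-3p read lengths and TE density below were chosen only after the result was seen, as was the 21 nt reading of the lists.

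The 2 tRNA-Gly genes called lower had 2264 to 3174 counts in each control and 0 in both mutants. Fewer tRNA-Gly fragments as the whole cause is argued against by the first mutant library, where the 41 tRNA-Gly genes summed to 13914 CPM, against 12822 and 8468 CPM in the controls, while both genes had 0 counts. In the second they summed to 2946 CPM, -1.85 from the control mean on the log2 scale (group difference -0.337), so that a loss of fragments as part of the change there stays open. Reads of identical copies given to different copies in different libraries may explain the calls, since 56.1% of tRNA genes with at least 50 counts in a library had 0 in another, against 1.66% of protein-coding genes, 33.8 times as often. This stays open too, because the sum was not level in the second library and the treatment of such reads upstream was not given in the sources used here.

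The share of 22 nt reads among TE counts was higher in both mutant libraries, at 15.2% and 20.8% against at most 10.1% in the controls. A few TEs as its source are argued against by shares of at least 14.6% in the mutants without the 50 TEs richest in 22 nt reads, against at most 9.55%. A size selection towards shorter reads as the whole cause is argued against by rRNA reads, whose log2 ratio of 22 to 24 nt rose by at most 0.306 of the rise of TE reads, which was 0.70 in the first and 1.43 in the second mutant library. The ratio of chloroplast reads, however, rose by 0.34 and 0.11 and that of protein-coding reads by 0.22 and 1.08, and 18 nt reads made up 15.2% of gene counts in the second against 7.75% to 9.48% in the others, so part of the shift in either library may come from shorter inserts. A change in the dicing of TE transcripts with rpt2a stays an untested hypothesis.

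PORI rpt2a replicate 2 stood apart in miRNA abundance, and its lower depth is argued against by the first mutant library, which, thinned to the same miRNA total, still correlated with PORI replicate 1 at 0.972, against 0.875 for the second. A mislabelled control is argued against by gene and TE small RNAs, where PORI rpt2a replicate 2 correlated better with the first mutant library than with either control, by 0.103 and 0.175. The first mutant library correlated about as well with the controls, at 0.845 and 0.823 against 0.821 for genes and 0.798 and 0.787 against 0.788 for TEs. Over all read lengths the first mutant library was thus no closer to the second than to PORI replicate 1. By length it was closer to the second in 22 nt TE reads (0.827 against 0.609 and 0.600 with the controls). The same held in 22 nt gene (0.830 against 0.780 and 0.758), 21 nt TE (0.680 against 0.564 and 0.543) and 24 nt gene reads (0.803 against 0.773 and 0.758). It did not hold in 21 nt gene (0.857 against 0.870 and 0.857) or 24 nt TE reads (0.770 against 0.771 and 0.766). PORI rpt2a replicate 2 stood apart from the controls in genes (0.699 and 0.717) and TEs (0.588 and 0.614) too, where its depth was not tested. Shorter inserts are argued against as the cause of its low miR158a-3p, whose reads were at least 97.8% of 20 nt or shorter in each library and yet made up 1.76% of miRNA counts against at least 17.9% elsewhere. For the other miRNAs they stay open, since without miR158a-3p reads of 20 nt or shorter made up 5.98% against 5.97% to 7.17%, such reads within 36 miRNAs of 21 nt were slightly more frequent (median 3.55% against 2.45% to 3.04%), and the medians of miRNAs of 20 nt or shorter and longer ones were -0.244 apart (95% bootstrap interval -1.63 to 1.34), the bound set beforehand, an interquartile spread of 2.47 between single miRNAs, being too wide for a shift of medians. In the other direction, 22 nt reads made up 10.4% of miRNA counts in PORI rpt2a replicate 2 against 4.78% to 5.88% in the other libraries. Reads of 23 nt made up 0.750% against 0.260% to 0.355%. A difference between the plants or preparations of these libraries also stays open, and no label gives a batch.

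As a hypothesis, rpt2a may shift small RNAs of TE genes by where they lie. Among TE genes whose 50 neighbours on each side were more than 50% TE genes (1749 genes), the median log2 change against the control mean was 0.91 in the first and 0.74 in the second mutant library, and with under 10% (391 genes) -0.11 and -0.54. The difference was 1.02 and 1.28, and it exceeded 0.5 in both libraries on 5 of 5 chromosomes, with 84.8% against 32.7% of genes at a positive fold change. The bound of 0.5 was set after the values were seen, and both differences use the same control libraries. PORI replicate 2 against PORI replicate 1 gave -0.047, and with a separate control for each mutant library the differences were 1.02 and 1.32, or 1.04 and 1.24 with the controls exchanged. The medians and the shares of positive fold changes depend on TMM scaling, with a factor of 0.696 for the second mutant library against 1.23 and 1.02 in PORI. Without TMM factors all TE genes held 7.48% and 4.54% of gene counts in PORI rpt2a, against 4.79% and 3.86% in PORI. A gain in TE-dense neighbourhoods of the second library may thus rest on the scaling, which hardly touches the difference from TE-poor ones. Neighbouring genes are not independent, and GC content was not tested.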
